A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

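RNA had been extracted with the MasterPure Yeast RNA kit, and the labels list cutadapt 1.9.1, HISAT2 2.0.1 and HTSeq 0.6.1 with genome build sacCer3, without stating their roles, their settings or the strand setting. The authors deposited 1 table of 7126 genes with whole-number counts per library, not normalised and not pooled. It also holds FPKM that the authors had computed per kilobase of the deposited exonic gene size and per total of the count column, which matched a recomputation from the counts within 0.005, the rounding of the table. The exonic gene size was deposited in bases and was used for the gene length test and for checking FPKM. Gene symbols came from the table, and where it gave none from the RefSeq annotation of the yeast genome.

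The groups were the 6 genotypes of the labels. Genes with FPKM of at least 1 in at least 2 of the 12 libraries were tested (6583 genes), and SET2, CHO2 and OPI1 were left out of counts and lists. Before the data were examined, limma on log2(FPKM + 1) had been fixed as the test, for a table expected to hold FPKM alone, together with the comparisons, the 26 gene lists, the rule for named genes and the alternatives not said to be added later. Since the table also held counts, the quasi-likelihood test of edgeR 4.0.16 on counts was used in its place, with TMM scaling (factors 0.897 to 1.077), CPM scaled by the same factors unless said otherwise, 1 mean per genotype, 6 residual degrees of freedom and a common biological coefficient of variation of 0.12. Tests were 2-sided, and p was adjusted by the Benjamini-Hochberg method over all genes tested, with 0.05 as the threshold. There were 10 comparisons of groups and 2 interaction terms, each the change with SET2 loss in a lipid mutant minus that in CHO2 OPI1 cells. The SE of a log2 change was taken as its size over the square root of the F statistic. With 2 libraries against 2, groups fail to overlap by chance in 33.3% of genes, and an exact permutation test of 1 gene cannot reach p < 0.05, so the tests draw on the spread pooled over genes and genotypes.

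Named genes were the deleted genes and, per comparison of groups, the 10 largest rises and 10 largest falls among genes with adjusted p < 0.05, groups that did not overlap and a mean FPKM of at least 5 in the higher group. For interaction terms they were 5 and 5, with a mean FPKM of at least 5 in any group and no rule on overlap; up to 4 members of each passing list with the largest changes were added, and the text gives a choice of these. Gene lists were tested with camera (limma 3.58.1) on the same fit with a correlation between genes preset at 0.01, adjusted over the 26 lists of a comparison, and again with an estimated correlation. Overlaps of calls between comparisons without a shared library were set against independent lists with Fisher's exact test, 2-sided. Pairs with a shared group were set against 100 simulated draws of unchanged groups around the same shared libraries, tested with limma. Genes with 0 counts in a group were given a bound from 3 counts in each library, and those with 1 to 3 counts a ratio with its counting interval.

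The alternatives were limma on log2(FPKM + 0.1), no filter on low values, median-of-ratios scaling, a replicate block, each library left out in turn and the estimated correlation. Added after the data were seen were camera on log2(FPKM + 1), DESeq2 1.42.0 and single libraries left out of list tests and overlaps. So was leaving the library labelled cho2set2 replicate 1 out of comparisons without its group and of lists with an estimated correlation. FPKM was not TMM-scaled, so both limma settings also change the scaling. Replicate numbers did not pair libraries: over 15 pairs of genotypes the correlation of the differences between replicates ran from -0.329 to 0.329 (median 0.008). In simulated data edgeR recovered 67.0% of 200 changed genes, with 30.8%, 75.4% and 93.9% at 1.5-, 2- and 4-fold. Of 141 calls, 7 were false. Of 25 random lists, no test of co-regulated ones, 1 passed with the preset and 0 with the estimated correlation. Raw reads were not used here. The work was done in R 4.3.3 and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.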

Results

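Transcript counts were available for 12 RNA-seq libraries of the yeast Saccharomyces cerevisiae, strain background CEN.PK, in 6 genotypes of 2 libraries each: wild type (WT), set2, cho2, opi1 and the double mutants cho2set2 and opi1set2. SET2 encodes the methyltransferase for lysine 36 of histone H3, CHO2 the enzyme that starts the methylation of phosphatidylethanolamine to phosphatidylcholine, and OPI1 the repressor of phospholipid genes that carry the inositol-sensitive promoter element (UAS-INO). Cells had grown in rich lactate medium (YPL) and were collected 1 h after a wash and transfer to minimal lactate medium (SL). Total counts per library ran from 7383001 to 9461609, and 6508 to 6570 genes had counts. A count of 0 allowed a level of up to 0.317 to 0.406 CPM (counts-per-million), the value of 3 counts in a library; this limit and the counting intervals cover counting error only. Nothing in the labels says that the 2 libraries of a genotype came from separate cultures, so the p-values measure the spread between these samples only. Numbers in parentheses after a gene symbol are log2 changes ± SE with 2 libraries in each group, coordinates are from the deposited table (genome build sacCer3), and the strand setting of the counting was not given, so counts of overlapping genes on opposite strands were not told apart.

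The deleted genes were low in the strains named for them, with 1 exception. SET2 (YJL168C, chromosome X, 102227 to 104428) had 153 and 181 counts in WT and 0 in both set2 and both opi1set2 libraries, and 239 and 149 in cho2. The library labelled cho2set2 replicate 1 held 50 SET2 counts, and replicate 2 held 0. CHO2 (YGR157W, chromosome VII, 802440 to 805049) had 3305 and 3320 counts in WT, 10 and 13 in cho2, and 2 and 4 in cho2set2. OPI1 (YHL020C, chromosome VIII, 66242 to 67456) had 980 and 1227 counts in WT, 0 and 0 in opi1 and 0 and 1 in opi1set2. For comparisons with cho2set2, the value after the comma that follows a gene's SE is therefore the log2 change without the library labelled cho2set2 replicate 1.

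**Figure D1:**
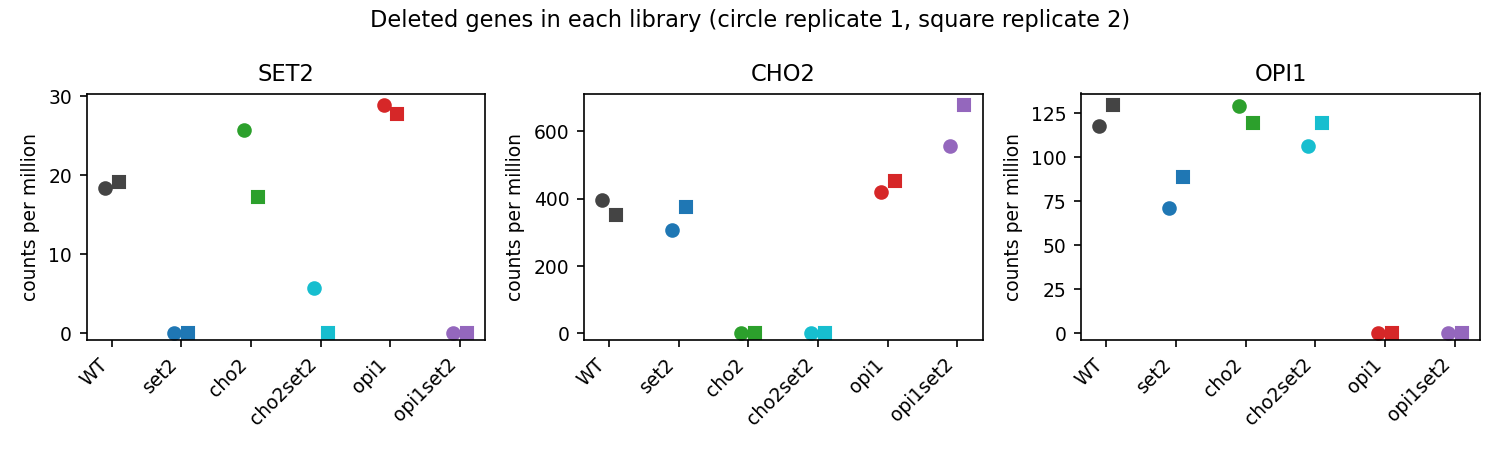
Levels of SET2, CHO2 and OPI1 in CPM without TMM scaling (vertical axes) in each library, by genotype, with circles for replicate 1 and squares for replicate 2. SET2 stood at 5.73 CPM in the library labelled cho2set2 replicate 1 and at 0 in the other libraries of set2 genotypes.

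The comparison of set2 with WT asked what loss of the H3K36 methyltransferase alone changed after the switch. DRS1 (YLL008W, chromosome XII, 131729 to 133987), a helicase of ribosome assembly, stood at 252 ± 31.4 CPM (mean ± SD, n = 2) in set2 and 11.2 ± 2.78 in WT, a log2 change of 4.50 ± 0.25 (SE; adjusted p = 8.17e-08). ARG1 (YOL058W, chromosome XV, 219211 to 220473), an enzyme of arginine synthesis, stood at 1100.4 ± 145 CPM in set2 and 99.0 ± 65.3 in WT, a log2 change of 3.48 ± 0.32 (adjusted p = 3.14e-06). Other large rises were those of MDN1 (3.47 ± 0.23), FLO10 (3.54 ± 0.23), BNR1 (3.40 ± 0.19) and HXT14 (4.65 ± 0.53), which encode a ribosome assembly ATPase, a flocculin, a formin and a hexose transporter-like protein; HXT14 overlaps another gene. STE3, the receptor for a-factor, was 84.9-fold (95% counting interval 29.1 to 412) lower, with 124 and 143 counts in WT and 2 and 1 in set2, and overlaps YKL177W. Falls were also found for IRC18 (-4.13 ± 0.52), SPR28 (-3.29 ± 0.36) and SSP1 (-3.15 ± 0.43). 1217 genes were higher and 1046 lower in set2 (2263 of 6580, adjusted p < 0.05), 624 of them by at least 2-fold. The total was 1446 without WT replicate 2 and 1272 without set2 replicate 1.

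Of 54 amino acid synthesis genes under Gcn4, 46 rose and 0 fell (46 and 1 adjusted over the list alone), among them ARG3 (2.63 ± 0.26) and LEU9 (2.90 ± 0.22); LEU9 overlaps another gene. Their median was 0.99 (adjusted p = 3.49e-21, and adjusted p = 0.246 with an estimated correlation). Among the 100 ribosome biogenesis genes, 54 rose and 3 fell (55 and 4 adjusted over the list alone), including NOP4 (3.30 ± 0.22), ERB1 (2.57 ± 0.22), RIX1 (2.52 ± 0.25) and NOP14 (2.32 ± 0.21); NOP4 overlaps YPL044C. Their median was 0.71 (adjusted p = 4.11e-14, and adjusted p = 0.466 with an estimated correlation). RPS26B (1.36 ± 0.24), RPL5 (1.31 ± 0.20) and RPL8A (1.28 ± 0.21) were among the 138 cytosolic ribosomal protein genes, of which 57 rose and 0 fell (62 and 0 adjusted over the list alone). Their median was 0.37 (adjusted p = 5.22e-06, and adjusted p = 0.698 with an estimated correlation). Genes with cryptic start sites under Set2 control rose in 10 and fell in 0 of 12 cases (11 and 0 adjusted over the list alone), with FLO8 (2.35 ± 0.18) and AVO1 (1.51 ± 0.19), which are read from internal promoters when H3K36 methylation is lost. Their median was 0.57 (adjusted p = 1.23e-05, and adjusted p = 0.0947 with an estimated correlation). Of 28 genes under nitrogen catabolite repression, 13 rose and 3 fell (14 and 3 adjusted over the list alone), among them PTR2 (2.98 ± 0.34), AGP1 (1.83 ± 0.35) and DUR1,2 (1.79 ± 0.15). Their median was 0.41 (adjusted p = 0.00789, and adjusted p = 0.252 with an estimated correlation).

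Among the 39 genes induced in the environmental stress response, 1 rose and 17 fell (1 and 21 adjusted over the list alone), including SSA4 (-1.43 ± 0.14) and SDP1 (-1.08 ± 0.20). Their median was -0.42 (adjusted p = 1.40e-05, and adjusted p = 0.532 with an estimated correlation). HTA1 (-1.11 ± 0.15), HHF1 (-0.82 ± 0.14), HHT1 (-0.80 ± 0.14) and HTA2 (-0.74 ± 0.15) were among the 10 histone genes, of which 0 rose and 8 fell (0 and 8 adjusted over the list alone). Their median was -0.64 (adjusted p = 0.000253, and adjusted p = 0.466 with an estimated correlation). Meiosis and sporulation genes rose in 1 and fell in 5 of 14 cases (1 and 6 adjusted over the list alone), with DMC1 (-2.63 ± 0.26) and IME1 (-1.68 ± 0.36). Their median was -0.63 (adjusted p = 0.00416, and adjusted p = 0.183 with an estimated correlation). Of 21 glycolysis and fermentation genes, 1 rose and 13 fell (2 and 15 adjusted over the list alone), among them TDH1 (-1.61 ± 0.30), TDH2 (-0.91 ± 0.19) and CDC19 (-0.87 ± 0.19). Their median was -0.46 (adjusted p = 0.00698, and adjusted p = 0.618 with an estimated correlation). Among the 26 iron regulon genes, 10 rose and 4 fell (11 and 5 adjusted over the list alone), including VHT1 (2.50 ± 0.26) and FRE1 (1.59 ± 0.15). Their median was 0.27 (adjusted p = 0.00653, and adjusted p = 0.466 with an estimated correlation). MRPL3 (1.17 ± 0.16) and RSM22 (1.13 ± 0.20) were among the 67 mitochondrial ribosomal protein genes, of which 23 rose and 1 fell (24 and 1 adjusted over the list alone). Their median was 0.28 (adjusted p = 0.00371, and adjusted p = 0.698 with an estimated correlation). With 1 library left out, adjusted p was at least 0.05 for the glycolysis and fermentation genes (0.0839) without set2 replicate 2.

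The comparison of cho2 with WT asked what loss of the phosphatidylethanolamine methyltransferase changed on its own. SAM1 (YLR180W, chromosome XII, 515262 to 516410), an S-adenosylmethionine (SAM) synthetase, stood at 67.9 ± 16.2 CPM (mean ± SD, n = 2) in cho2 and 489 ± 12.2 in WT, a log2 change of -2.85 ± 0.30 (SE; adjusted p = 8.58e-05). MET6 (YER091C, chromosome V, 339864 to 342167), the methionine synthase, stood at 1114 ± 327 CPM in cho2 and 6279 ± 937 in WT, a log2 change of -2.49 ± 0.28 (adjusted p = 0.000157). Enzymes of sulfur assimilation and of methionine and cysteine synthesis fell with them, as in STR3 (-2.58 ± 0.33), CYS3 (-2.50 ± 0.29), MET1 (-2.46 ± 0.36), MET3 (-2.32 ± 0.32) and MET14 (-2.28 ± 0.34). So did the permease AGP3 (-2.27 ± 0.27) and the pyruvate decarboxylase isozyme PDC6 (-2.20 ± 0.24). Large rises were those of YDL057W (2.32 ± 0.16) and ALP1 (2.11 ± 0.31), which encode a protein of unknown function and an arginine transporter. INO1 (YJL153C, chromosome X, 134332 to 135933), the enzyme of inositol synthesis, rose from 243 ± 18.4 to 611 ± 169 CPM (1.33 ± 0.19, adjusted p = 0.000834). 16 genes were higher and 97 lower in cho2 (113 of 6580, adjusted p < 0.05), 66 of them by at least 2-fold. The total was 64 without cho2 replicate 2, and 184 by DESeq2, with 31.0% of the calls higher against 14.2% by edgeR.

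Sulfate assimilation and methionine genes rose in 0 and fell in 23 of 25 cases (0 and 24 adjusted over the list alone). Their median was -1.96 (adjusted p = 1.37e-89, and adjusted p = 0.0169 with an estimated correlation). Of 21 genes of the SAM cycle, transsulfuration and glutathione, 0 rose and 8 fell (0 and 9 adjusted over the list alone), with CYS3, STR3 and MHT1 standing in both lists. Their median was -0.18 (adjusted p = 3.92e-15, and adjusted p = 0.011 with an estimated correlation). Among the 10 histone genes, 0 rose and 3 fell (0 and 5 adjusted over the list alone), including HTA2 (-1.22 ± 0.15), HHF2 (-1.15 ± 0.14) and HTB2 (-1.09 ± 0.14). Their median was -0.35 (adjusted p = 4.33e-09, and adjusted p = 0.239 with an estimated correlation). The 19 UAS-INO phospholipid genes held 3 that rose and 0 that fell (4 and 0 adjusted over the list alone), INO1 among them. Their median was 0.27 (adjusted p = 3.59e-05, and adjusted p = 0.288 with an estimated correlation). Amino acid synthesis genes under Gcn4 rose in 0 and fell in 4 of 54 cases (0 and 11 adjusted over the list alone), with SER33 (-1.84 ± 0.21) and SER1 (-0.80 ± 0.12). Their median was -0.22 (adjusted p = 2.32e-06, and adjusted p = 0.648 with an estimated correlation). Adjusted p was at least 0.05 with 1 library left out for the amino acid synthesis genes under Gcn4 (0.605) without WT replicate 1.

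The comparison of opi1 with WT asked what loss of the phospholipid gene repressor changed on its own. INO1 (YJL153C, chromosome X, 134332 to 135933) stood at 16021 ± 344 CPM (mean ± SD, n = 2) in opi1 and 243 ± 18.4 in WT, a log2 change of 6.04 ± 0.23 (SE; adjusted p = 4.07e-10). CHO1 (YER026C, chromosome V, 207644 to 208474), the phosphatidylserine synthase, stood at 1419.5 ± 109 CPM in opi1 and 243 ± 0.800 in WT, a log2 change of 2.55 ± 0.13 (adjusted p = 9.94e-09), and the inositol transporter ITR1 rose with it (2.41 ± 0.18). Further rises were those of MF(ALPHA)1 (4.92 ± 0.37), ECM8 (2.46 ± 0.21), URA10 (2.45 ± 0.19) and SPO11 (3.22 ± 0.15), encoding alpha-factor, a protein of unknown function, an orotate phosphoribosyltransferase isozyme and a meiotic recombination protein; SPO11 (chromosome VIII, 62961 to 64157) lies close to the deleted OPI1. Large falls were those of BDS1 (-3.70 ± 0.25), AGP3 (-3.70 ± 0.29), MUP1 (-3.21 ± 0.35), MET1 (-3.28 ± 0.38), MET3 (-3.20 ± 0.33) and CYS3 (-3.13 ± 0.30), and of PDC6 (-3.66 ± 0.26) and GRX8 (-3.51 ± 0.19), a pyruvate decarboxylase isozyme and a glutaredoxin. 588 genes were higher and 577 lower in opi1 (1165 of 6580, adjusted p < 0.05), 314 of them by at least 2-fold. The total was 508 without WT replicate 1, 758 without opi1 replicate 1 and 448 without opi1 replicate 2. Of the calls 50.5% were higher, against 30.0% on FPKM without TMM scaling, where the median over all genes lay at -0.14.

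Of 19 UAS-INO phospholipid genes, 16 rose and 0 fell (16 and 0 adjusted over the list alone), among them CDS1 (2.39 ± 0.15). Their median was 1.17 (adjusted p = 4.23e-42, and adjusted p = 0.00608 with an estimated correlation). Among the 25 sulfate assimilation and methionine genes, 0 rose and 23 fell (0 and 23 adjusted over the list alone). Their median was -2.37 (adjusted p = 6.85e-40, and adjusted p = 0.101 with an estimated correlation). HTA2 (-2.47 ± 0.16), HTB2 (-2.31 ± 0.15) and HHF2 (-2.16 ± 0.14) were among the 10 histone genes, of which 0 rose and 7 fell (0 and 7 adjusted over the list alone). Their median was -0.63 (adjusted p = 1.36e-10, and adjusted p = 0.133 with an estimated correlation). Amino acid synthesis genes under Gcn4 rose in 1 and fell in 27 of 54 cases (1 and 30 adjusted over the list alone), with SER33 (-2.70 ± 0.22), HOM3 (-2.45 ± 0.36) and GDH1 (-2.07 ± 0.19). Their median was -0.49 (adjusted p = 1.56e-09, and adjusted p = 0.37 with an estimated correlation). Of 100 ribosome biogenesis genes, 0 rose and 30 fell (0 and 31 adjusted over the list alone). Their median was -0.52 (adjusted p = 3.94e-08, and adjusted p = 0.52 with an estimated correlation).

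Among the 29 peroxisome and beta-oxidation genes, 14 rose and 1 fell (16 and 1 adjusted over the list alone), including ECI1 (1.23 ± 0.14) and IDP3 (0.83 ± 0.15). Their median was 0.47 (adjusted p = 8.65e-06, and adjusted p = 0.322 with an estimated correlation). ATG7 (1.04 ± 0.13) and ATG39 (0.91 ± 0.16) were among the 39 autophagy genes, of which 8 rose and 0 fell (8 and 0 adjusted over the list alone). Their median was 0.20 (adjusted p = 0.000182, and adjusted p = 0.322 with an estimated correlation). Genes of the SAM cycle, transsulfuration and glutathione rose in 2 and fell in 7 of 21 cases (3 and 8 adjusted over the list alone), with SAM1 (-2.77 ± 0.30) and MHT1 (-2.58 ± 0.26). Their median was -0.32 (adjusted p = 0.00137, and adjusted p = 0.133 with an estimated correlation). Of 26 sterol synthesis genes, 2 rose and 10 fell (3 and 10 adjusted over the list alone), among them ERG3 (-1.39 ± 0.14), ERG11 (-1.11 ± 0.16) and ERG4 (-1.10 ± 0.15). Their median was -0.25 (adjusted p = 0.00597, and adjusted p = 0.436 with an estimated correlation).

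The comparison of cho2set2 with cho2 asked what loss of SET2 changed in cells without CHO2, and its directions draw on the library labelled cho2set2 replicate 1. NOP4 (YPL043W, chromosome XVI, 469939 to 471996), a nucleolar protein of ribosome maturation that overlaps YPL044C, stood at 312 ± 109 CPM (mean ± SD, n = 2) in cho2set2 and 25.4 ± 4.35 in cho2, a log2 change of 3.62 ± 0.22 (SE; adjusted p = 2.08e-07), and 3.9 without that library. DRS1 (4.02 ± 0.25, 4.3) and MDN1 (3.40 ± 0.22, 3.7) of ribosome assembly rose too, as did FLO10 (3.41 ± 0.24, 3.6), BNR1 (3.17 ± 0.19, 3.4) and HXT14 (4.82 ± 0.52, 5.1). Falls were found for IRC18 (-2.44 ± 0.42, -4.0), LOH1 (-2.25 ± 0.36, -2.6) and SSP1 (-1.95 ± 0.38, -2.6), and for STE3 (-2.62 ± 0.39, -4.1), GAL7 (-2.11 ± 0.37, -2.9) and MCH2 (-1.96 ± 0.30, -2.9), a pheromone receptor, an enzyme of galactose use and a monocarboxylate permease-like protein. 742 genes were higher and 367 lower in cho2set2 (1109 of 6580, adjusted p < 0.05), 349 of them by at least 2-fold. Without the library labelled cho2set2 replicate 1, 1038 genes were called, 716 higher and 322 lower, and 50 of the 61 genes named by rule or as list examples stayed past the threshold. The total was 605 without cho2 replicate 1, 647 without cho2 replicate 2 and 492 without cho2set2 replicate 2.

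Among the 100 ribosome biogenesis genes, 33 rose and 1 fell (40 and 2 adjusted over the list alone), including RIX1 (2.35 ± 0.25, 2.5), SPB1 (2.19 ± 0.21, 2.4) and ENP2 (1.99 ± 0.22, 2.2). Their median was 0.42 (adjusted p = 1.20e-11, and adjusted p = 0.42 with an estimated correlation) and was 0.48 (adjusted p = 2.83e-10) without the library labelled cho2set2 replicate 1. TDH1 (-1.69 ± 0.30, -2.5) and CDC19 (-1.24 ± 0.20, -1.5) were among the 21 glycolysis and fermentation genes, of which 1 rose and 13 fell (1 and 16 adjusted over the list alone). Their median was -0.58 (adjusted p = 1.12e-07, and adjusted p = 0.42 with an estimated correlation) and was -0.68 (adjusted p = 4.41e-08) without that library. Genes with cryptic start sites under Set2 control rose in 6 and fell in 0 of 12 cases (9 and 0 adjusted over the list alone), with FLO8 (1.71 ± 0.18, 1.8) and SPB4 (1.49 ± 0.16, 1.5). Their median was 0.50 (adjusted p = 2.82e-06, and adjusted p = 0.0719 with an estimated correlation) and was 0.56 (adjusted p = 1.62e-05) without that library.

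Of 19 UAS-INO phospholipid genes, 0 rose and 7 fell (0 and 7 adjusted over the list alone), among them INO1 (-1.41 ± 0.19, -1.5) and OPI3 (-0.91 ± 0.15, -1.1). Their median was -0.21 (adjusted p = 0.00756, and adjusted p = 0.42 with an estimated correlation) and was -0.14 (adjusted p = 0.06) without the library labelled cho2set2 replicate 1. Among the 43 respiratory chain and ATP synthase genes, 11 rose and 1 fell (15 and 1 adjusted over the list alone), including ATP20 (1.03 ± 0.17, 1.0). Their median was 0.36 (adjusted p = 0.0029, and adjusted p = 0.59 with an estimated correlation) and was 0.35 (adjusted p = 0.0697) without that library. Leaving out 1 library took adjusted p to at least 0.05 for the respiratory chain and ATP synthase genes (0.0836) without cho2 replicate 1.

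The comparison of opi1set2 with opi1 asked what loss of SET2 changed in cells without OPI1, and it gave the most calls of the 12 comparisons. DRS1 (YLL008W, chromosome XII, 131729 to 133987) stood at 202 ± 16.7 CPM (mean ± SD, n = 2) in opi1set2 and 4.39 ± 1.80 in opi1, a log2 change of 5.53 ± 0.29 (SE; adjusted p = 2.24e-08). ADY2 (YCR010C, chromosome III, 132273 to 133124), an acetate transporter, stood at 768 ± 0.870 CPM in opi1set2 and 11374 ± 1353 in opi1, a log2 change of -3.89 ± 0.20 (adjusted p = 2.24e-08). Rises were also found for YHB1 (3.93 ± 0.33), MDN1 (3.80 ± 0.24), ARG1 (3.75 ± 0.33), BNR1 (3.66 ± 0.19) and LEU9 (3.74 ± 0.26). Falls were found for FAT3 (-3.19 ± 0.22), PMA2 (-3.17 ± 0.28) and IRC18 (-3.61 ± 0.45). GAT3, a GATA zinc finger protein, was 13.3-fold (95% counting interval 4.56 to 64.6) lower. 1546 genes were higher and 1368 lower in opi1set2 (2914 of 6580, adjusted p < 0.05), 950 of them by at least 2-fold. Of the calls 53.1% were higher, against 72.2% on FPKM without TMM scaling, where the median over all genes lay at 0.19.

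RIX1 (3.51 ± 0.27), UTP5 (3.27 ± 0.19) and PWP2 (3.24 ± 0.29) were among the 100 ribosome biogenesis genes, of which 83 rose and 2 fell (84 and 3 adjusted over the list alone). Their median was 1.45 (adjusted p = 2.67e-30, and adjusted p = 0.367 with an estimated correlation). Amino acid synthesis genes under Gcn4 rose in 44 and fell in 1 of 54 cases (44 and 1 adjusted over the list alone), with SNZ1 (2.79 ± 0.16). Their median was 0.96 (adjusted p = 1.09e-15, and adjusted p = 0.367 with an estimated correlation). Of 138 cytosolic ribosomal protein genes, 117 rose and 0 fell (126 and 0 adjusted over the list alone), among them RPS26B (2.17 ± 0.25), RPL3 (1.88 ± 0.30) and RPS9A (1.51 ± 0.28). Their median was 0.69 (adjusted p = 6.79e-13, and adjusted p = 0.572 with an estimated correlation). Among the 25 sulfate assimilation and methionine genes, 22 rose and 1 fell (22 and 1 adjusted over the list alone), including MUP1 (3.31 ± 0.35) and CYS3 (2.35 ± 0.30). Their median was 1.22 (adjusted p = 5.42e-07, and adjusted p = 0.561 with an estimated correlation). CYC1 (1.92 ± 0.21), ATP20 (1.78 ± 0.17) and NDE2 (-1.60 ± 0.14) were among the 43 respiratory chain and ATP synthase genes, of which 32 rose and 2 fell (32 and 2 adjusted over the list alone). Their median was 0.65 (adjusted p = 3.05e-05, and adjusted p = 0.561 with an estimated correlation).

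Peroxisome and beta-oxidation genes rose in 1 and fell in 21 of 29 cases (1 and 21 adjusted over the list alone), with IDP3 (-2.29 ± 0.16) and CTA1 (-2.12 ± 0.20). Their median was -0.88 (adjusted p = 4.47e-14, and adjusted p = 0.231 with an estimated correlation). Of 12 genes with cryptic start sites under Set2 control, 6 rose and 1 fell (6 and 1 adjusted over the list alone), among them FLO8 (2.19 ± 0.18) and SPB4 (1.75 ± 0.16). Their median was 0.41 (adjusted p = 0.000707, and adjusted p = 0.231 with an estimated correlation). Among the 24 genes of lactate use, gluconeogenesis and the glyoxylate cycle, 4 rose and 11 fell (6 and 11 adjusted over the list alone), and the median turned to 0.06 on FPKM without TMM scaling. Their median was -0.13 (adjusted p = 0.000896, and adjusted p = 0.495 with an estimated correlation).

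**Figure D2:**
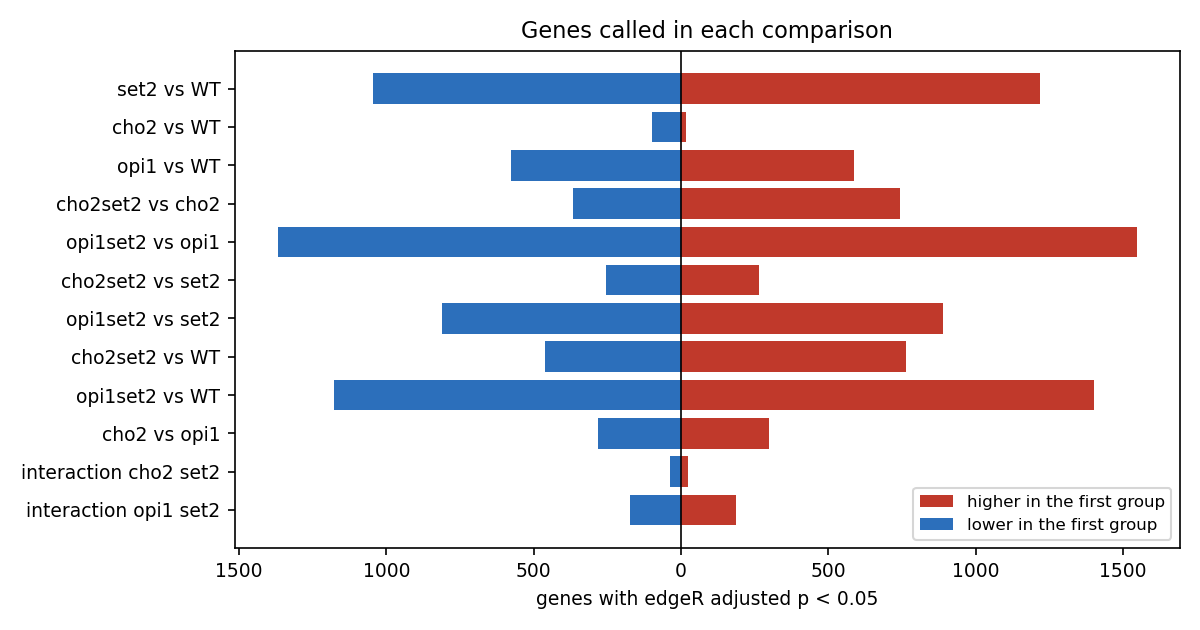
Number of genes with an edgeR adjusted p under 0.05 (horizontal axis) in each of the 12 comparisons, with red bars to the right for genes higher and blue bars to the left for genes lower in the first group, or for positive and negative interaction terms. The bars reach 1546 and 1368 in opi1set2 vs opi1 and 16 and 97 in cho2 vs WT.

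The comparison of cho2set2 with set2 asked what loss of CHO2 changed in cells without SET2, and its directions draw on the library labelled cho2set2 replicate 1. ARG1 (YOL058W, chromosome XV, 219211 to 220473) stood at 108 ± 10.8 CPM (mean ± SD, n = 2) in cho2set2 and 1100.4 ± 145 in set2, a log2 change of -3.35 ± 0.32 (SE; adjusted p = 1.09e-05), and -3.2 without that library. FDH1 (YOR388C, chromosome XV, 1071793 to 1072923), a formate dehydrogenase with the close paralogs YPL276W and FDH2, stood at 1599 ± 80.1 CPM in cho2set2 and 177 ± 2.33 in set2, a log2 change of 3.17 ± 0.17 (adjusted p = 6.23e-08), and 3.1 without that library. Falls were found for ARG3 (-3.12 ± 0.27, -3.0), STR3 (-3.08 ± 0.34, -2.6), YCT1 (-3.05 ± 0.19, -2.8), HOM3 (-2.71 ± 0.36, -2.2), JLP1 (-2.65 ± 0.19, -2.5), MET1 (-2.65 ± 0.36, -2.2) and PDC6 (-2.61 ± 0.25, -2.7). Rises were found for ALP1 (2.46 ± 0.32, 2.5), SPR28 (2.36 ± 0.37, 1.6), DMC1 (2.34 ± 0.26, 2.0), SNO4 (2.00 ± 0.21, 1.6) and ADY2 (1.97 ± 0.18, 2.0). 264 genes were higher and 255 lower in cho2set2 (519 of 6580, adjusted p < 0.05), 164 of them by at least 2-fold. Without the library labelled cho2set2 replicate 1, 190 genes were called, 80 higher and 110 lower, and 33 of the 46 genes named by rule or as list examples stayed past the threshold. The total was also 195 without set2 replicate 1. Of the calls 50.9% were higher, against 36.1% on FPKM without TMM scaling.

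The 54 amino acid synthesis genes under Gcn4 held 0 that rose and 43 that fell (0 and 46 adjusted over the list alone). Their median was -0.88 (adjusted p = 3.47e-59, and adjusted p = 0.0439 with an estimated correlation) and was -0.85 (adjusted p = 1.22e-51, and adjusted p = 0.0725 with an estimated correlation) without the library labelled cho2set2 replicate 1. Sulfate assimilation and methionine genes rose in 0 and fell in 24 of 25 cases (0 and 25 adjusted over the list alone). Their median was -1.71 (adjusted p = 2.10e-46, and adjusted p = 0.0603 with an estimated correlation) and was -1.30 (adjusted p = 1.15e-43) without that library. Of 21 genes of the SAM cycle, transsulfuration and glutathione, 1 rose and 10 fell (3 and 12 adjusted over the list alone), among them SAM1 (-2.54 ± 0.29, -2.1). Their median was -0.54 (adjusted p = 1.71e-10, and adjusted p = 0.0321 with an estimated correlation) and was -0.72 (adjusted p = 5.20e-11, and adjusted p = 0.0523 with an estimated correlation) without that library. Among the 29 peroxisome and beta-oxidation genes, 11 rose and 1 fell (15 and 1 adjusted over the list alone), including ECI1 (1.29 ± 0.14, 1.3), IDP3 (1.22 ± 0.15, 1.2) and DCI1 (1.12 ± 0.14, 1.2). Their median was 0.40 (adjusted p = 4.30e-10, and adjusted p = 0.22 with an estimated correlation) and was 0.33 (adjusted p = 2.16e-12) without that library.

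The comparison of opi1set2 with set2 asked what loss of OPI1 changed in cells without SET2. INO1 (YJL153C, chromosome X, 134332 to 135933) stood at 13908 ± 2828 CPM (mean ± SD, n = 2) in opi1set2 and 157 ± 10.1 in set2, a log2 change of 6.47 ± 0.24 (SE; adjusted p = 4.15e-10). Phospholipid genes CHO1 (3.05 ± 0.13) and OPI3 (2.92 ± 0.16) rose with it, as did MF(ALPHA)1 (6.15 ± 0.40), IME1 (2.97 ± 0.36) and SPO11 (4.22 ± 0.17), encoding alpha-factor and regulators or enzymes of meiosis. STE3 was 17.7-fold (95% counting interval 6.05 to 85.8) higher. Large falls were those of JLP1 (-4.18 ± 0.20), PDC6 (-4.14 ± 0.27), AGP3 (-3.67 ± 0.29), BDS1 (-3.40 ± 0.24) and YCT1 (-2.54 ± 0.18), followed by TOS6 (-2.25 ± 0.25), GRX8 (-2.23 ± 0.18) and MAL11 (-2.25 ± 0.19); MAL11 overlaps YGR290W. 888 genes were higher and 810 lower in opi1set2 (1698 of 6580, adjusted p < 0.05), 343 of them by at least 2-fold. The total was 761 without set2 replicate 1, 1124 without set2 replicate 2 and 818 without opi1set2 replicate 2.

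The 19 UAS-INO phospholipid genes held 16 that rose and 1 that fell (16 and 1 adjusted over the list alone). Their median was 1.66 (adjusted p = 4.05e-48, and adjusted p = 0.00251 with an estimated correlation). Sulfate assimilation and methionine genes rose in 0 and fell in 19 of 25 cases (0 and 22 adjusted over the list alone), with MET3 (-1.88 ± 0.31). Their median was -1.19 (adjusted p = 1.22e-11, and adjusted p = 0.456 with an estimated correlation). Of 54 amino acid synthesis genes under Gcn4, 2 rose and 30 fell (2 and 35 adjusted over the list alone), among them LYS20 (-2.05 ± 0.26) and ARG3 (-1.47 ± 0.25). Their median was -0.53 (adjusted p = 8.40e-08, and adjusted p = 0.573 with an estimated correlation).

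The comparison of cho2set2 with WT gave the joint change after loss of both genes, and its directions draw on the library labelled cho2set2 replicate 1. NOP4 (4.35 ± 0.23, 4.7), DRS1 (3.91 ± 0.25, 4.2), MDN1 (3.46 ± 0.23, 3.8), FLO10 (3.20 ± 0.23, 3.4) and BNR1 (2.87 ± 0.18, 3.1) rose, and PDC6 (-3.29 ± 0.25, -3.4), FMO1 (-2.64 ± 0.21, -2.5) and STR3 (-2.23 ± 0.33, -1.8) fell. Among the 25 sulfate assimilation and methionine genes, 0 rose and 23 fell (0 and 23 adjusted over the list alone). Their median was -1.57 (adjusted p = 4.08e-23, and adjusted p = 0.26 with an estimated correlation) and was -1.17 (adjusted p = 7.28e-13) without the library labelled cho2set2 replicate 1. RIX1 (2.36 ± 0.25, 2.5) and NOP14 (2.31 ± 0.21, 2.5) were among the 100 ribosome biogenesis genes, of which 46 rose and 0 fell (55 and 1 adjusted over the list alone). Their median was 0.63 (adjusted p = 6.56e-19, and adjusted p = 0.364 with an estimated correlation) and was 0.68 (adjusted p = 1.45e-16) without that library. Genes of the SAM cycle, transsulfuration and glutathione rose in 0 and fell in 11 of 21 cases (0 and 13 adjusted over the list alone). Their median was -0.52 (adjusted p = 5.97e-07, and adjusted p = 0.0487 with an estimated correlation) and was -0.68 (adjusted p = 5.58e-05, and adjusted p = 0.159 with an estimated correlation) without that library. Of 12 genes with cryptic start sites under Set2 control, 7 rose and 0 fell (10 and 0 adjusted over the list alone), among them FLO8 (2.01 ± 0.18, 2.1). Their median was 0.61 (adjusted p = 8.59e-07, and adjusted p = 0.0487 with an estimated correlation) and was 0.68 (adjusted p = 4.90e-06, and adjusted p = 0.0855 with an estimated correlation) without that library. 763 genes were higher and 460 lower in cho2set2 (1223 of 6580, adjusted p < 0.05), 396 of them by at least 2-fold. Without the library labelled cho2set2 replicate 1, 1103 genes were called, 704 higher and 399 lower, and 61 of the 69 genes named by rule or as list examples stayed past the threshold. The total was 690 without WT replicate 2 and 601 without cho2set2 replicate 2.

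The comparison of opi1set2 with WT gave the joint change after loss of both genes. INO1 (5.84 ± 0.23), MF(ALPHA)1 (5.42 ± 0.36), DRS1 (4.18 ± 0.25), BNR1 (3.22 ± 0.18) and HXT6 (4.18 ± 0.23) rose, HXT6 being a hexose transporter with close paralogs, and PDC6 (-4.83 ± 0.27), AGP3 (-3.69 ± 0.29), BDS1 (-3.17 ± 0.24), GRX8 (-3.07 ± 0.18) and IRC18 (-2.81 ± 0.45) fell. Among the 19 UAS-INO phospholipid genes, 16 rose and 2 fell (16 and 2 adjusted over the list alone), including CHO1 (3.03 ± 0.13) and HNM1 (2.98 ± 0.20). Their median was 1.41 (adjusted p = 1.27e-26, and adjusted p = 0.0208 with an estimated correlation), with the last p at 0.0588 without the library labelled cho2set2 replicate 1. NOP4 (2.89 ± 0.22) and RIX1 (2.75 ± 0.25) were among the 100 ribosome biogenesis genes, of which 67 rose and 2 fell (69 and 2 adjusted over the list alone). Their median was 0.91 (adjusted p = 7.48e-18, and adjusted p = 0.388 with an estimated correlation). Genes with cryptic start sites under Set2 control rose in 10 and fell in 0 of 12 cases (10 and 0 adjusted over the list alone), with FLO8 (2.29 ± 0.18). Their median was 0.69 (adjusted p = 1.08e-05, and adjusted p = 0.0466 with an estimated correlation), with the last p at 0.0609 without the library labelled cho2set2 replicate 1. 1401 genes were higher and 1179 lower in opi1set2 (2580 of 6580, adjusted p < 0.05), 732 of them by at least 2-fold. The total was 1537 without WT replicate 2.

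The direct comparison of cho2 with opi1 tested where the single lipid mutants differed. INO1 stood at 611 ± 169 CPM (mean ± SD, n = 2) in cho2 and 16021 ± 344 in opi1, a log2 change of -4.71 ± 0.22 (SE; adjusted p = 2.82e-09), and MF(ALPHA)1 (-5.18 ± 0.38), SPO11 (-3.52 ± 0.16), GIC2 (-2.51 ± 0.37) and ICP55 (-2.30 ± 0.16) were lower in cho2 as well. Higher in cho2 were PCL1 (2.46 ± 0.22), GDH1 (2.20 ± 0.19), AGP1 (2.20 ± 0.38), RNR1 (2.17 ± 0.15) and LYS20 (2.01 ± 0.27). Of 19 UAS-INO phospholipid genes, 0 rose and 15 fell (0 and 15 adjusted over the list alone), among them CHO1 (-2.28 ± 0.13). Their median was -1.13 (adjusted p = 1.43e-42, and adjusted p = 0.00398 with an estimated correlation). Among the 100 ribosome biogenesis genes, 33 rose and 0 fell (62 and 0 adjusted over the list alone), including DBP3 (1.75 ± 0.28). Their median was 0.67 (adjusted p = 4.03e-21, and adjusted p = 0.422 with an estimated correlation). 298 genes were higher and 281 lower in cho2 (579 of 6580, adjusted p < 0.05), 196 of them by at least 2-fold. The total was 216 without cho2 replicate 1, 353 without cho2 replicate 2, 338 without opi1 replicate 1 and 166 without opi1 replicate 2. Of the calls 51.5% were higher, against 65.7% on FPKM without TMM scaling.

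**Figure D3:**
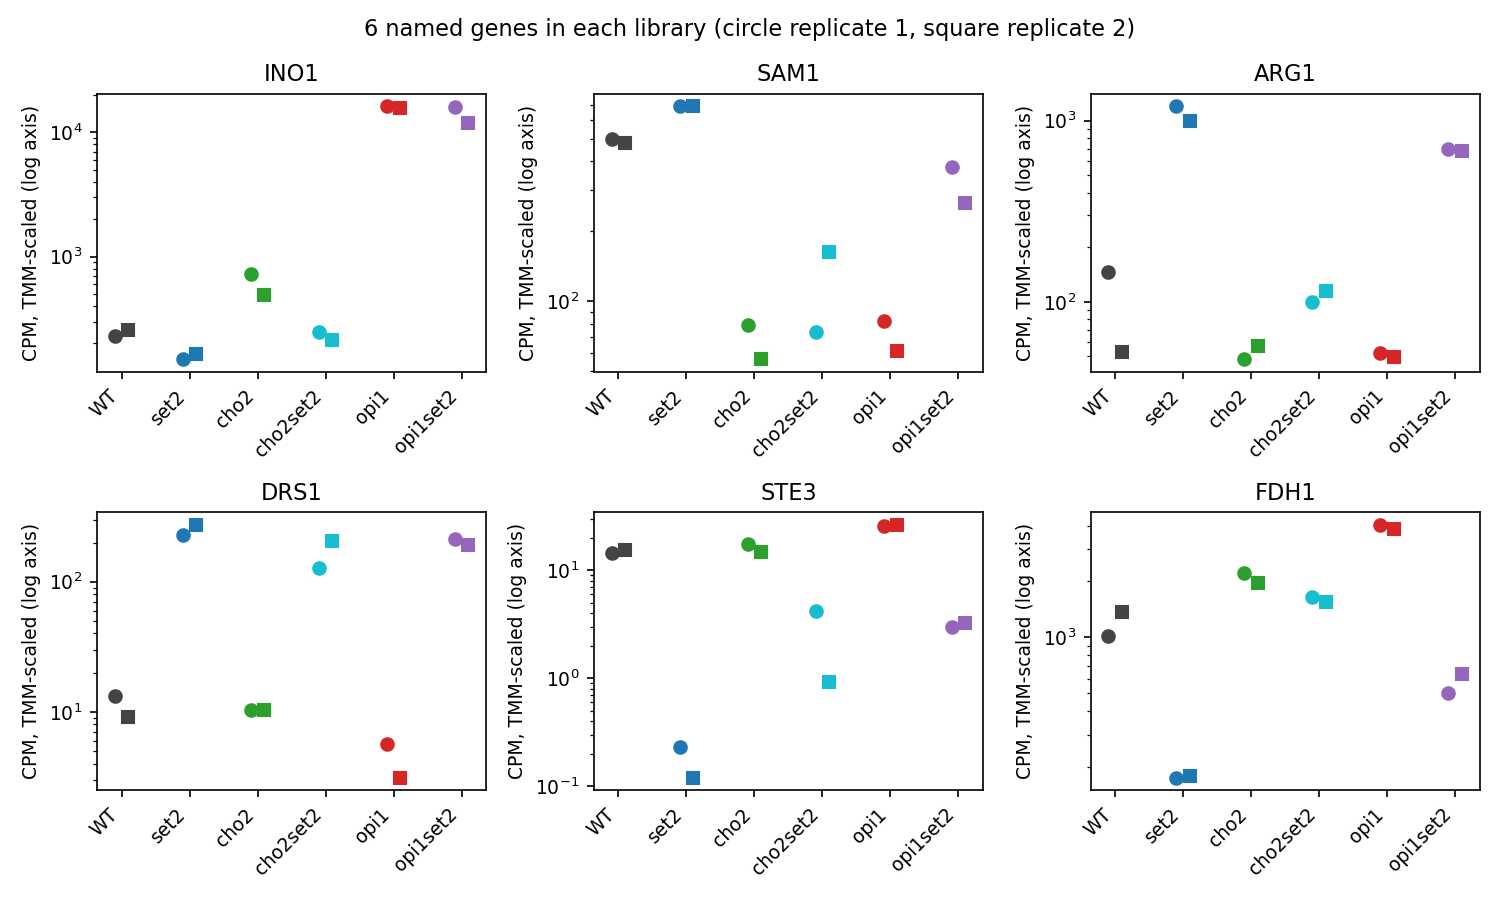
Levels of INO1, SAM1, ARG1, DRS1, STE3 and FDH1 in TMM-scaled CPM (log axes) in each library, by genotype, with circles for replicate 1 and squares for replicate 2. INO1 averaged 16021 CPM in opi1 and 243 in WT, and ARG1 averaged 1100.4 CPM in set2 and 108 in cho2set2.

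The interaction term of cho2 and set2 tested whether the change after SET2 loss differed between cells without and with CHO2, and it draws on the library labelled cho2set2 replicate 1. ARG1 (YOL058W) had a mean of 99.0 ± 65.3 CPM in WT and 1100.4 ± 145 in set2, against 52.6 ± 6.12 in cho2 and 108 ± 10.8 in cho2set2, an interaction of -2.44 ± 0.43 (adjusted p = 0.0119), and of -2.3 without that library. Terms below 0 were also found for VHT1 (-2.70 ± 0.37, -2.5), ARG3 (-2.40 ± 0.37, -2.3) and YDL057W (-2.35 ± 0.22, -2.4), and terms above 0 for FDH1 (2.36 ± 0.23, 2.3) and DMC1 (2.14 ± 0.34, 1.8). Of 54 amino acid synthesis genes under Gcn4, 0 had passing terms above 0 and 16 below (1 and 37 adjusted over the list alone). The median was -0.75 (adjusted p = 1.11e-37, and adjusted p = 0.135 with an estimated correlation) and was -0.66 (adjusted p = 6.88e-31) without the library labelled cho2set2 replicate 1. Passing terms of the 10 histone genes numbered 5 above and 0 below 0 (7 and 0 adjusted over the list alone), including HTA2 (1.62 ± 0.21, 1.5) and HHF2 (1.48 ± 0.20, 1.4). The median was 0.85 (adjusted p = 1.17e-12, and adjusted p = 0.135 with an estimated correlation) and was 0.70 (adjusted p = 1.47e-11) without that library. Of 138 cytosolic ribosomal protein genes, 0 had passing terms above 0 and 1 below (0 and 20 adjusted over the list alone). The median was -0.38 (adjusted p = 3.81e-15, and adjusted p = 0.727 with an estimated correlation) and was -0.45 (adjusted p = 4.67e-22) without that library. 60 genes passed (24 with terms above 0 and 36 below, 50 of at least 2-fold), 14 without the library labelled cho2set2 replicate 1, when 8 of 18 named genes and examples stayed. The total was also 107 without WT replicate 1, 25 without WT replicate 2, 9 without set2 replicate 1, 22 without cho2 replicate 1 and 25 without cho2 replicate 2, 18 and 15 by limma on log2(FPKM + 1) and log2(FPKM + 0.1), and 127 by DESeq2, which moved the share above 0 from 40.0% to 54.3%. With 1 library left out, adjusted p was at least 0.05 for ARG1 (0.0546) without cho2 replicate 2, for ARG1 (0.1) and ARG3 (0.0617) without the library labelled cho2set2 replicate 1, and for ARG1 (0.114), ARG3 (0.0667) and DMC1 (0.0903) without set2 replicate 1.

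The interaction term of opi1 and set2 tested whether the change after SET2 loss differed between cells without and with OPI1. ADY2 (YCR010C), an acetate transporter, stood at 2670.1 ± 487 CPM in WT, 1003 ± 158 in set2, 11374 ± 1353 in opi1 and 768 ± 0.870 in opi1set2, an interaction of -2.48 ± 0.25 (adjusted p = 0.000242). Terms below 0 were also found for FAT3 (-2.20 ± 0.29), HXT2 (-1.88 ± 0.25) and YDL057W (-2.37 ± 0.22), and terms above 0 for YHB1 (2.62 ± 0.42) and YKL068W-A (2.70 ± 0.40), encoding a flavohemoglobin and a protein of unknown function. Passing terms of the 29 peroxisome and beta-oxidation genes numbered 0 above and 13 below 0 (0 and 18 adjusted over the list alone), including FOX2 (-1.69 ± 0.22). The median was -0.70 (adjusted p = 7.09e-16, and adjusted p = 0.313 with an estimated correlation). Of 100 ribosome biogenesis genes, 10 had passing terms above 0 and 0 below (43 and 0 adjusted over the list alone), among them NOP53 (1.65 ± 0.28). The median was 0.70 (adjusted p = 1.14e-14, and adjusted p = 0.364 with an estimated correlation). Passing terms of the 25 sulfate assimilation and methionine genes numbered 8 above and 0 below 0 (18 and 1 adjusted over the list alone). The median was 1.15 (adjusted p = 8.51e-10, and adjusted p = 0.364 with an estimated correlation).

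Of 10 histone genes, 4 had passing terms above 0 and 0 below (6 and 0 adjusted over the list alone). The median was 0.56 (adjusted p = 3.53e-05, and adjusted p = 0.364 with an estimated correlation). Passing terms of the 28 chaperone genes under Hsf1 numbered 4 above and 0 below 0 (8 and 0 adjusted over the list alone). The median was 0.26 (adjusted p = 0.00171, and adjusted p = 0.364 with an estimated correlation). In this interaction term of opi1 and set2 360 genes passed (187 with terms above 0 and 173 below, 190 of at least 2-fold). The total was 76 without WT replicate 1, 608 without WT replicate 2, 54 without set2 replicate 1, 131 without set2 replicate 2, 76 without opi1 replicate 1, 44 without opi1 replicate 2, 1144 without opi1set2 replicate 1 and 129 without opi1set2 replicate 2, 189 and 184 by limma on log2(FPKM + 1) and log2(FPKM + 0.1), and 615 by DESeq2. Of the calls 51.9% had terms above 0, against 73.0% on FPKM without TMM scaling, where the median term lay at 0.15.

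**Figure D4:**
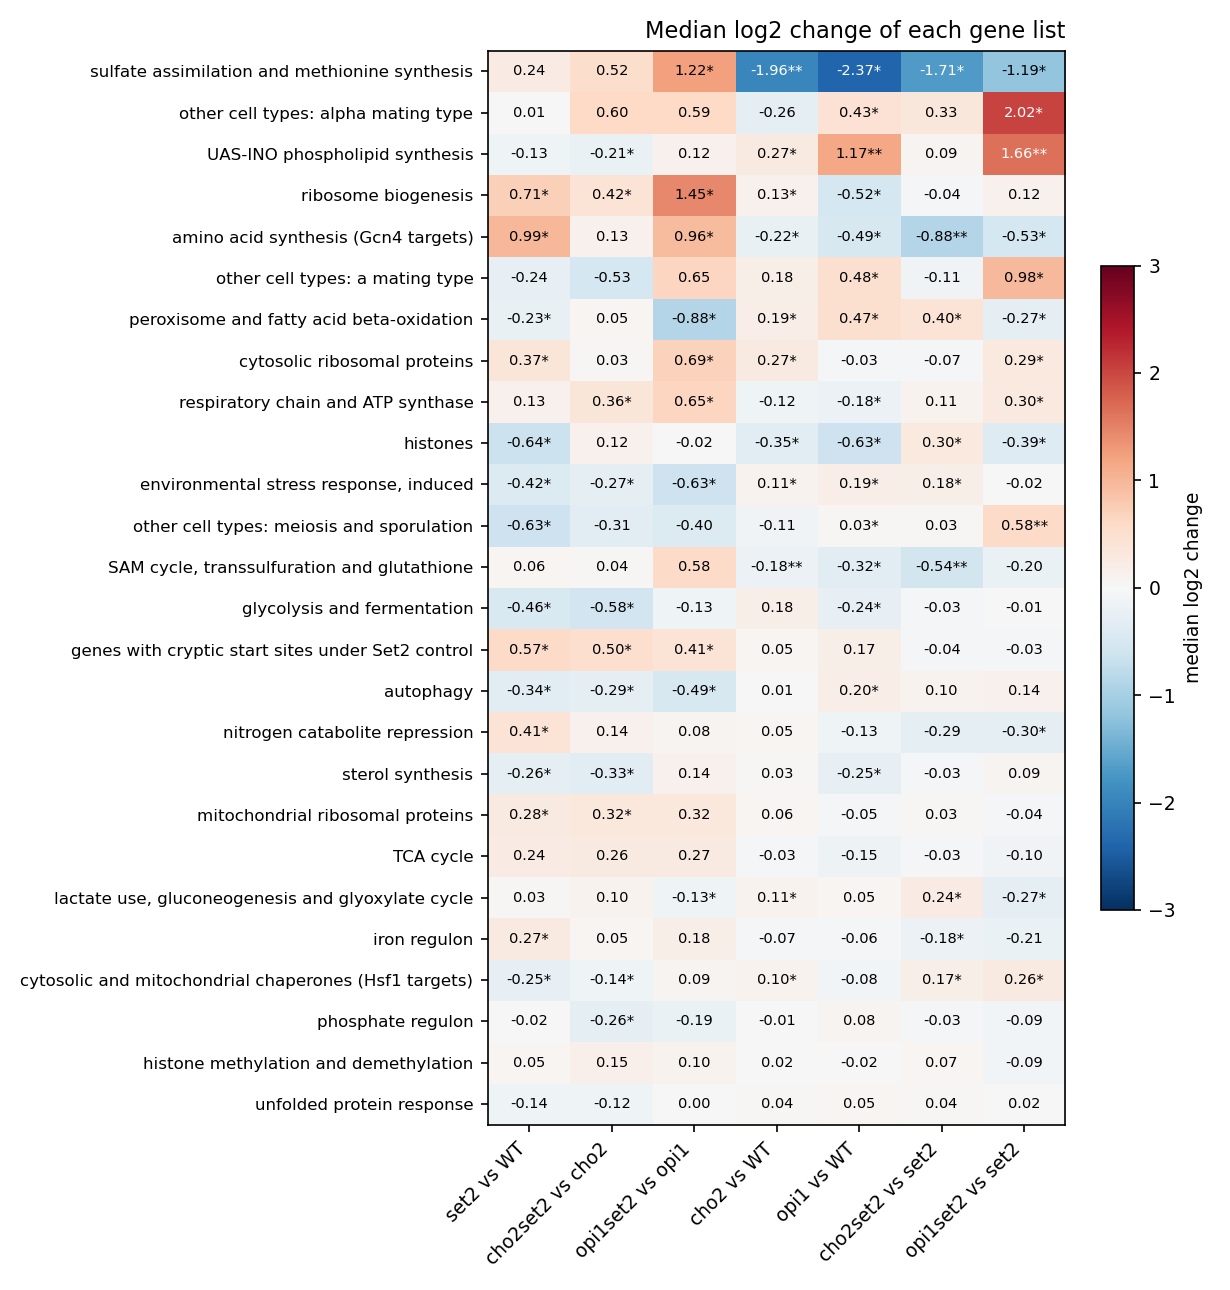
Median log2 change (colour scale, with the value in each cell) of the 26 gene lists (vertical axis) in 7 comparisons (horizontal axis). 1 star marks a camera adjusted p under 0.05 and a pair of stars one that also passes with an estimated correlation, as for the UAS-INO list in opi1 vs WT (1.17) and the sulfate and methionine list in cho2 vs WT (-1.96).

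Of 26 gene lists tested in 12 comparisons by camera with a preset correlation of 0.01, 149 calls passed, and 13 held with an estimated correlation. Those were the genes of the SAM cycle, transsulfuration and glutathione in cho2 vs WT, cho2set2 vs set2 and cho2set2 vs WT, the sulfate assimilation and methionine genes in cho2 vs WT, the UAS-INO phospholipid genes in opi1 vs WT, opi1set2 vs set2, opi1set2 vs WT and cho2 vs opi1, the amino acid synthesis genes under Gcn4 in cho2set2 vs set2, the meiosis and sporulation genes in opi1set2 vs set2 and cho2 vs opi1 and the genes with cryptic start sites under Set2 control in cho2set2 vs WT and opi1set2 vs WT. Without the library labelled cho2set2 replicate 1, 7 of the calls held with an estimated correlation, none of them in a comparison with cho2set2. The TCA cycle list, of 23 genes, passed in no comparison, with its lowest adjusted p (0.073, median 0.26) in cho2set2 vs cho2, where 4 rose and 0 fell (6 and 0 adjusted over the list alone). The unfolded protein response list, of 25 genes, passed in no comparison, with its lowest adjusted p (0.0778, median -0.12) in cho2set2 vs cho2, where 1 rose and 3 fell (1 and 3 adjusted over the list alone). The list of histone methylation and demethylation, of 18 genes, passed in no comparison, with its lowest adjusted p (0.0778, median 0.15) in cho2set2 vs cho2, where 4 rose and 0 fell (5 and 0 adjusted over the list alone). In no passing list did the median and mean, or the median and the test, differ in sign; in other lists the median and mean differed in sign in 0 to 3 lists per comparison, such as the alpha mating type genes in set2 vs WT (median 0.01, mean -1.28, adjusted p = 0.528).

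The changes after SET2 loss were compared between backgrounds that share no library, with 2-sided Fisher's exact tests; genes are not independent replicates. DRS1, MDN1 and BNR1 were among the genes higher in all 3 backgrounds, and IRC18 among those lower. For set2 vs WT and cho2set2 vs cho2, 616 genes were higher and 281 lower in both, where independent lists would share 137 and 58.3 (Fisher's exact test, p of at most 1e-300 and p = 6.18e-160), with Pearson r = 0.556 and Spearman rho = 0.635 across 6580 genes. Shared genes numbered 551 without cho2 replicate 1, 573 without cho2 replicate 2 and 439 without cho2set2 replicate 2. For set2 vs WT and opi1set2 vs opi1, 906 genes were higher and 593 lower in both, where independent lists would share 286 and 218 (Fisher's exact test, p of at most 1e-300 and p = 1.24e-178), with Pearson r = 0.598 and Spearman rho = 0.617 across 6580 genes. Shared genes numbered 991 without WT replicate 2. For cho2set2 vs cho2 and opi1set2 vs opi1, 622 genes were higher and 248 lower in both, where independent lists would share 174 and 76.3 (Fisher's exact test, p of at most 1e-300 and p = 2.86e-89), with Pearson r = 0.497 and Spearman rho = 0.582 across 6580 genes. Shared genes numbered 535 without cho2 replicate 1, 528 without cho2 replicate 2 and 430 without cho2set2 replicate 2. Without the library labelled cho2set2 replicate 1 the first and the last pair shared 903 and 832 genes in the same direction, against 897 and 870 with it.

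The changes after loss of CHO2 or OPI1 were compared with and without SET2 in the same way. PDC6, STR3, MET1 and ALP1 were called in the same direction in cho2 vs WT and cho2set2 vs set2, and INO1, CHO1, BDS1 and AGP3 in opi1 vs WT and opi1set2 vs set2. For cho2 vs WT and cho2set2 vs set2, 11 genes were higher and 71 lower in both, where independent lists would share 0.60 and 3.80 (Fisher's exact test, p = 1.29e-12 and p = 2.38e-82), with Pearson r = 0.176 and Spearman rho = 0.191 across 6580 genes. Shared genes numbered 52 without cho2 replicate 2 and Pearson r was 0.109 without WT replicate 1. Without the library labelled cho2set2 replicate 1 this pair shared 57 genes. For opi1 vs WT and opi1set2 vs set2, 297 genes were higher and 221 lower in both, where independent lists would share 79.4 and 71.0 (Fisher's exact test, p = 9.53e-118 and p = 1.15e-64), with Pearson r = 0.342 and Spearman rho = 0.348 across 6580 genes. Shared genes numbered 326 without WT replicate 1, 339 without set2 replicate 1 and 261 without opi1 replicate 2. For cho2 vs WT and opi1set2 vs set2, 7 genes were higher and 56 lower in both, where independent lists would share 2.20 and 11.9 (Fisher's exact test, p = 0.003 and p = 5.85e-27), with Pearson r = 0.110 and Spearman rho = 0.113 across 6580 genes. Pearson r was 0.0630 without WT replicate 2, 0.0680 without set2 replicate 2 and 0.0720 without cho2 replicate 1.

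Pairs of comparisons with a shared group were set against simulated unchanged groups, since the shared libraries alone link them; that group was not split, since each part would hold 1 library, so part of any excess is not separated from them. SAM1, CYS3, MET3, PDC6 and AGP3 were lower and INO1 was higher in both cho2 and opi1 against the shared WT, where 10 genes were higher and 86 lower in both and 0 in opposite directions (independent lists would share 1.4 and 8.5), with a covariance of 0.104 and Pearson r of 0.546 on log CPM against 0.0320 and 0.501 simulated. The shared count was 54 without cho2 replicate 2. Against the shared opi1, 332 genes were higher in opi1 vs WT and lower in opi1set2 vs opi1, as was the peroxisomal IDP3, and 377 the reverse, as were MUP1 and CYS3, where independent lists would share 122.2 and 135.6, with a covariance of -0.215 and r of -0.496 against -0.0320 and -0.501 simulated. The shared count was 297 without WT replicate 1, 420 without opi1 replicate 1 and 256 without opi1 replicate 2. Against the shared cho2, 9 and 20 genes moved in opposite directions in cho2 vs WT and cho2set2 vs cho2, with INO1 among the first (0.9 and 10.9 for independent lists), and the covariance was -0.0430 and r -0.232 against -0.0310 and -0.499 simulated; without the library labelled cho2set2 replicate 1 they numbered 36 together. Their number was 16 without cho2 replicate 1, 15 without cho2 replicate 2 and 19 without cho2set2 replicate 2.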

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

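Both tests of the source of the SET2 counts, and leaving that library out of list tests, were chosen after those counts were seen. The library labelled cho2set2 replicate 1 held 50 SET2 counts (5.62 CPM, 25.6% of the cho2 mean of 22.0), where a deleted gene should have none and cho2set2 replicate 2 had 0. Material of a strain with intact CHO2 would have brought CHO2 transcripts, and the library held 2 CHO2 counts, 0.237% of the level needed (at most 0.857% by the counting interval), which argues against that source. Material of a cho2 strain with intact SET2 is a candidate. Over 429 genes moved at least 2-fold by SET2 loss in both other backgrounds, the median log2 change was smaller by a share of 0.289 (0.222 to 0.314, bootstrap) than in replicate 2. On a log scale, it is not comparable with 25.6%. In set2 and opi1set2 it was -0.0218 to 0.0213 (270 and 282 genes chosen alike). A mixed culture, a mixed library and a culture with cells that had kept SET2 would look alike in these counts, and no biological explanation was tested.

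Amino acid synthesis genes under Gcn4 rose with SET2 loss in WT cells (46 of 54 rose and 0 fell, median 0.99, adjusted p = 3.49e-21, and adjusted p = 0.246 with an estimated correlation), while in cho2 cells the list did not pass (9 rose and 1 fell, median 0.13, adjusted p = 0.0778, and adjusted p = 0.796 with an estimated correlation). The median interaction was -0.75 (adjusted p = 1.11e-37, and adjusted p = 0.135 with an estimated correlation). It was -0.66 without the library labelled cho2set2 replicate 1 and -0.58 without WT replicate 2, the smaller of the values without a WT library, so neither that library nor 1 WT library accounted for it. Over all alternatives it ran from -0.87 to -0.58, with adjusted p = 0.219 at most, with an estimated correlation and without the library labelled cho2set2 replicate 1. A weaker response of the Gcn4 program to SET2 loss in cells without CHO2 may underlie it, as a hypothesis found and tested on the same data. Differences in growth or in the timing of the response after the medium switch stay open, untested.

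The other differences between backgrounds come from the interaction terms. For cho2 and set2, 60 genes passed, 14 without the library labelled cho2set2 replicate 1, 107 without WT replicate 1, 25 without WT replicate 2, 9 without set2 replicate 1, 22 without cho2 replicate 1 and 25 without cho2 replicate 2. The named terms, with the value without that library in parentheses, were FDH1 2.36 (2.30), YPL276W 2.25 (2.32), SPR28 2.21 (1.43), DMC1 2.14 (1.77), YER087C-A 2.10 (2.06), VHT1 -2.70 (-2.47), ARG1 -2.44 (-2.34), ARG3 -2.40 (-2.27), YDL057W -2.35 (-2.35) and ARO5 -2.09 (-1.89); FDH1 and YPL276W are paralogs, and YPL276W and YER087C-A overlap other genes. List medians were histones 0.85 (0.70), meiosis 0.29 (0.31), respiratory chain 0.21 (0.15), peroxisome 0.17 (0.20), ribosome biogenesis -0.18 (-0.14), glycolysis -0.19 (-0.31), nitrogen repression -0.21 (-0.16), iron -0.23 (-0.19) and ribosomal proteins -0.38 (-0.45), each with an adjusted p of at least 0.135 with an estimated correlation. Adjusted p was at least 0.05 with 1 library left out for the respiratory chain list (0.481), the glycolysis list (0.0778), the nitrogen repression list (0.0535) and the iron list (0.0778) without WT replicate 1, for SPR28 (0.149), YER087C-A (0.21), the ribosome biogenesis list (0.933), the glycolysis list (0.0599) and the nitrogen repression list (0.093) without WT replicate 2, for SPR28 (0.103), YER087C-A (0.176), the respiratory chain list (0.388) and the ribosome biogenesis list (0.37) without cho2 replicate 1, and for SPR28 (0.125), YER087C-A (0.135), ARG1 (0.0546), the glycolysis list (0.469), the nitrogen repression list (0.237) and the iron list (0.0872) without cho2 replicate 2. It also did so for SPR28 (0.206), YER087C-A (0.176), ARG1 (0.1), ARG3 (0.0617), ARO5 (0.0871), the respiratory chain list (0.0501), the nitrogen repression list (0.0526) and the iron list (0.0852) without the library labelled cho2set2 replicate 1, for YER087C-A (0.0648), the glycolysis list (0.478) and the nitrogen repression list (0.0581) without cho2set2 replicate 2, for YPL276W (0.0848), SPR28 (0.39), DMC1 (0.0903), YER087C-A (0.116), ARG1 (0.114), ARG3 (0.0667), ARO5 (0.0903), the glycolysis list (0.28), the nitrogen repression list (0.0618) and the iron list (0.175) without set2 replicate 1, and for SPR28 (0.05), YER087C-A (0.109), the respiratory chain list (0.0507) and the nitrogen repression list (0.0548) without set2 replicate 2. The median of the respiratory list was 0 without WT replicate 1, and that of the ribosome biogenesis list turned to 0.03 without WT replicate 2.

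For opi1 and set2, 360 genes passed, and 76 without WT replicate 1, 608 without WT replicate 2, 54 without set2 replicate 1, 131 without set2 replicate 2, 76 without opi1 replicate 1, 44 without opi1 replicate 2, 1144 without opi1set2 replicate 1 and 129 without opi1set2 replicate 2. The named terms were STE3 3.22, YNL276C 2.82, YKL068W-A 2.70, YHB1 2.62, MUP1 2.45, ADY2 -2.48, YDL057W -2.37, FAT3 -2.20, YJR027W -2.0 and HXT2 -1.88; STE3 had 2 and 1 counts in set2, so its fitted value depends on the prior count, and STE3, YNL276C and YJR027W overlap other genes. List medians were sulfate and methionine 1.15, ribosome biogenesis 0.70, histones 0.56, SAM cycle 0.55, respiratory chain 0.47, sterol 0.45, UAS-INO 0.37, ribosomal proteins 0.30, meiosis 0.27, chaperones 0.26, stress response -0.17, lactate -0.24 and peroxisome -0.70, each with an adjusted p of at least 0.313 with an estimated correlation. Leaving out 1 library took adjusted p to at least 0.05 for STE3 (0.116), YJR027W (0.14), the ribosomal proteins list (0.666) and the stress response list (0.554) without WT replicate 1, for the UAS-INO list (0.0996) and the meiosis list (0.0508) without WT replicate 2, for STE3 (0.104), YNL276C (0.0532), YJR027W (0.113) and the UAS-INO list (0.0553) without opi1 replicate 1, and for STE3 (0.121), YNL276C (0.0758), MUP1 (0.0705), YJR027W (0.104) and the stress response list (0.0923) without opi1 replicate 2. It also did so for the UAS-INO list (0.172), the meiosis list (0.144) and the stress response list (0.102) without opi1set2 replicate 1, for STE3 (0.0913) and YJR027W (0.0658) without opi1set2 replicate 2, for STE3 (0.16), YNL276C (0.0595), MUP1 (0.0599), YJR027W (0.13) and the stress response list (0.0567) without set2 replicate 1, and for STE3 (0.154), MUP1 (0.0502), YJR027W (0.0777), the UAS-INO list (0.222) and the meiosis list (0.062) without set2 replicate 2.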

How the results depend on the processing

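Limma on log2(FPKM + 1) was fixed before the data were seen. Camera on it, DESeq2 and single libraries left out of list tests, overlaps and correlations came later. So did omitting the library labelled cho2set2 replicate 1 where its group is absent or with an estimated correlation. No gene named by rule or as a list example reversed in any alternative; of 670, 668 kept direction and call with median-of-ratios scaling, 665 without a filter, 653 by DESeq2, 615 by limma on log2(FPKM + 1) and 601 on log2(FPKM + 0.1). Leaving out 1 library, the share of those it bears on ran from 68.7% without opi1 replicate 2 to 97.6% without opi1set2 replicate 1; the lone sample left in a group is then assumed to vary like the other groups. Of 149 list calls, 149, 147, 141 and 139 held with median-of-ratios scaling, without a filter and on log2(FPKM + 1) and log2(FPKM + 0.1). Depth limits genes with few counts, such as STE3 in set2, whose folds are given as ratios with counting intervals, and the cause of the changes below was not tested.

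With a replicate block 646 of 670 genes and 146 of 149 lists kept their calls.

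Numbers of called genes, lowest to highest with 1 library left out, were set2 vs WT 1272 to 2275, cho2 vs WT 64 to 118, opi1 vs WT 448 to 1165, cho2set2 vs cho2 492 to 1038, opi1set2 vs opi1 2082 to 2907, cho2set2 vs set2 190 to 521, opi1set2 vs set2 761 to 2167, cho2set2 vs WT 601 to 1103, opi1set2 vs WT 1537 to 2605, cho2 vs opi1 166 to 601, interaction cho2 set2 9 to 107 and interaction opi1 set2 44 to 1144, and the list calls numbered 140 to 152. Most counts fell, but that of the cho2 interaction rose without WT replicate 1, and that of the opi1 interaction without WT replicate 2 or opi1set2 replicate 1. Replicates were least alike in opi1set2 (r 0.985, others at least 0.991), untested as a cause. By DESeq2 there were 184 calls in cho2 vs WT and 127 and 615 in the cho2 and opi1 interactions. By limma these had 18 and 189 on log2(FPKM + 1) and 15 and 184 on log2(FPKM + 0.1). Of the 149 list calls 13 held with an estimated correlation and 7 also without the library labelled cho2set2 replicate 1.

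Shared calls, lowest to highest with 1 library left out, were 439 to 903 for set2 vs WT with cho2set2 vs cho2, 991 to 1546 for set2 vs WT with opi1set2 vs opi1, 430 to 914 for cho2set2 vs cho2 with opi1set2 vs opi1, 52 to 83 for cho2 vs WT with cho2set2 vs set2, 261 to 589 for opi1 vs WT with opi1set2 vs set2, 47 to 71 for cho2 vs WT with opi1set2 vs set2, 54 to 97 for cho2 vs WT with opi1 vs WT, 15 to 36 for cho2 vs WT with cho2set2 vs cho2 and 256 to 759 for opi1 vs WT with opi1set2 vs opi1. Pearson r ran from 0.460 to 0.560, 0.501 to 0.609, 0.406 to 0.487, 0.109 to 0.176, 0.276 to 0.351, 0.0630 to 0.124, 0.412 to 0.624, -0.532 to -0.241 and -0.560 to -0.362 in the same order; the last 3 pairs share a group, which alone gave 0.501, -0.499 and -0.501 in simulations on log CPM. DESeq2 gave 130 shared calls for cho2 vs WT with cho2set2 vs set2 and 51 for cho2 vs WT with cho2set2 vs cho2, where limma on log2(FPKM + 1) gave 17. In that order, for the first 8 pairs, Pearson r was 0.681, 0.690, 0.627, 0.326, 0.475, 0.173, 0.556 and -0.247 by limma on log2(FPKM + 1) and 0.719, 0.665, 0.656, 0.438, 0.517, 0.220, 0.574 and -0.197 by DESeq2. Without a filter it was 0.493, 0.543, 0.453, 0.144, 0.306 and 0.0860 for the first 6 pairs, and limma on log2(FPKM + 0.1) gave 0.145 for cho2 vs WT with cho2set2 vs set2; the cause was not tested.

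Medians of passing lists that turned sign or reached 0 with 1 library left out, for which the cause was not tested, were in cho2 vs WT those of the stress response (-0.04 without WT replicate 1 to 0.24 without WT replicate 2), lactate (-0.05 without cho2 replicate 2 to 0.21 without WT replicate 1) and ribosome biogenesis lists (-0.09 without WT replicate 2 to 0.41 without WT replicate 1). In opi1 vs WT it was that of the stress response list (-0.01 without WT replicate 1 to 0.36 without WT replicate 2), and in the interaction of cho2 and set2 those of the respiratory (0 without WT replicate 1 to 0.37 without cho2 replicate 2) and ribosome biogenesis lists (-0.43 without WT replicate 1 to 0.03 without WT replicate 2). On both FPKM scales with limma, the meiosis list lay at -0.11 in opi1 vs WT and the lactate list at 0.06 in opi1set2 vs opi1; the cause was not tested.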

Other observations

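The counts of called genes near chromosome ends outside set2 vs WT and the test of length in single pairs of libraries were chosen only after results were seen. Some mating genes were higher without OPI1. MF(ALPHA)1, the alpha-factor gene, stood at 35.8 ± 4.78 CPM (mean ± SD, n = 2) in opi1 and 1.17 in WT, and the a-cell genes STE2 (0.70 ± 0.14), AGA2 (0.69 ± 0.16), MFA2 (0.84 ± 0.24) and MFA1 (0.48 ± 0.16) rose beside it, while MF(ALPHA)2 (-0.93 ± 0.29) fell; against set2, opi1set2 showed rises of MFA2 (1.73 ± 0.24), MFA1 (1.36 ± 0.16) and STE2 (1.13 ± 0.13). In opi1 vs WT, 4 of 7 a mating type genes rose and 0 fell (4 and 0 adjusted over the list alone), with a median of 0.48 (adjusted p = 0.0346, and adjusted p = 0.436 with an estimated correlation). In opi1set2 vs set2, 4 of 7 a mating type genes rose and 0 fell (4 and 0 adjusted over the list alone), with a median of 0.98 (adjusted p = 0.000147, and adjusted p = 0.232 with an estimated correlation). In opi1 vs WT, 1 of 4 alpha mating type genes rose and 1 fell (2 and 1 adjusted over the list alone), with a median of 0.43 (adjusted p = 0.00924, and adjusted p = 0.133 with an estimated correlation). In opi1set2 vs set2, 2 of 4 alpha mating type genes rose and 0 fell (2 and 1 adjusted over the list alone), with a median of 2.02, which depends on STE3 with its 2 and 1 counts in set2 (adjusted p = 0.000945, and adjusted p = 0.086 with an estimated correlation). Against WT, 6 a and 3 alpha genes rose in opi1set2 and 1 and 1 fell. With 1 library left out, adjusted p was at least 0.05 for MFA2 (0.13), MFA1 (0.158) and MF(ALPHA)2 (0.181) without WT replicate 1, for MFA2 (0.0852), MFA1 (0.19), MF(ALPHA)2 (0.0629) and the a mating type genes (0.102) without WT replicate 2, for MFA2 (0.139), MFA1 (0.106), MF(ALPHA)2 (0.127) and the a mating type genes (0.0651) without opi1 replicate 1, and for AGA2 (0.0545), MFA2 (0.0797), MFA1 (0.317) and MF(ALPHA)2 (0.193) without opi1 replicate 2.

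Some meiosis genes were higher too, SPO11 (3.22 ± 0.15) and DMC1 (1.07 ± 0.21) with opi1 against WT and SPO11 (4.22 ± 0.17), IME1 (2.97 ± 0.36), DMC1 (1.61 ± 0.27) and SPR3 (1.31 ± 0.28) with opi1set2 against set2; SPO11 lies close to the deleted OPI1. In opi1 vs WT, 4 of 14 meiosis and sporulation genes rose and 0 fell (4 and 1 adjusted over the list alone), with a median of 0.03 that turned to -0.11 on FPKM without TMM scaling (adjusted p = 0.00213, and adjusted p = 0.101 with an estimated correlation). In opi1set2 vs set2, 6 of 14 meiosis and sporulation genes rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.58 (adjusted p = 4.47e-06, and adjusted p = 0.0242 with an estimated correlation).

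Longer genes tended to be higher in set2 than in WT (Spearman rho = 0.373 across 6580 genes, 0.241 and 0.0870 for SET2 loss in cho2 and opi1 cells); genes are not independent replicates. The relation was 0.459 at a given WT level, which argues against lower expression of longer genes as its source. In the 4 pairs of 1 set2 with 1 WT library rho ran from 0.294 (0.271 to 0.319, bootstrap) to 0.421, which argues against a length bias of 1 of these libraries. Between 2 libraries of a genotype rho was 0.433 in cho2set2, -0.23 in opi1set2, 0.0970 in WT and -0.154 in set2. So replicates outside set2 vs WT can differ by length, also in opi1set2, which lacks the library labelled cho2set2 replicate 1. A length bias of more than 1 library and loss of H3K36 methylation over long genes both stay open, untested.

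The hypothesis that genes within 20 kb of a chromosome end change more often without SET2 was not borne out in set2 vs WT: 36.0% of 225 such genes were called and 34.4% of the others, a ratio of 1.05, with 41 higher and 40 lower; the ratio was 1.28 in cho2set2 vs cho2, where it stays undecided, and 0.929 in opi1set2 vs opi1. The same count in cho2 vs WT gave 6.7% and 1.5%, a ratio of 4.31 (1.13 in opi1 vs WT), with 14 lower, among them AGP3, MMP1, BDS1 and MHT1 of amino acid and sulfur use, and 1 higher, FDH1. Chromosome ends were taken at the last gene of the table.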
